A study of Mus musculus with 6 samples.

How the data were processed

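DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in 6 mouse libraries of C57BL/6 background. RRBS cleaves genomic DNA with the enzyme MspI, which recognises CCGG, keeps a size fraction, converts unmethylated cytosines with bisulfite and sequences the products. CpG-dense sequence is therefore covered far more than the rest of the genome. The libraries were 2 wild-type lines of androgenetic haploid embryonic stem cells (WT AG-haESC), 3 lines labelled as double knockouts (DKO AG-haESC) and 1 sample of round spermatids, the haploid male germ cells that follow meiosis. AG-haESCs come from androgenetic blastocysts and hold a single set of chromosomes, of paternal origin. Per the labels, the lines grew on feeder cells in ES medium with 2i, a pair of kinase inhibitors that keep ES cells undifferentiated. The elements labelled as deleted are the H19 DMR and the IG-DMR, the differentially methylated regions that control the H19-Igf2 and Dlk1-Meg3 imprinted domains.

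Per the labels' protocols, MspI fragments were end-repaired, joined to methylated adapters, selected by size on an agarose gel, treated with bisulfite and amplified by PCR. The submitters' processing notes name Bismark 0.12.2 and the genome build mm10. Read trimming, removal of duplicates and the choice of cytosine context are not given in the sources used here. Each deposited file lists cytosine positions with a count of methylated reads, a count of unmethylated reads and the methylation level as a fraction from 0 to 1. The deposited fraction matched the methylated count over both counts at every position of the 6 files, within a tolerance of 1e-09. Neither strand nor sequence context stands beside a position, so whether every position is a CpG cytosine and correctly aligned was not checked here, and other cytosines among them would lower the levels. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Read counts of a window or chromosome were summed over its positions, so a read that covers several cytosines counts at each. Intervals and limits treat these counts as independent and are too narrow where that happens.

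Total read counts over cytosines were 227097459 and 255726544 in WT replicates 1 and 2. They were 201982492, 205637856 and 197728785 in DKO replicates 1, 2 and 3, and 293920118 in the round spermatid library. Of 2091599 positions seen in any library, 233019 had at least 10 reads in all 6 libraries and 264362 in all 5 lines, while 857968 reached 10 reads in exactly 1 library. No pair of libraries was a copy, as between 0.126% and 0.254% of shared cytosines had identical counts. Pearson's r of the levels across shared cytosines lay between 0.280 and 0.426 for pairs of lines, where cytosines are not independent replicates. The cause of these low correlations and of the many positions covered in a single library was not tested. The labels name the lines as separate without saying that they come from separate embryos, and titles of a WT and a DKO line share the name OG3 (WT replicate 1, DKO replicate 2) or AGH-2 (WT replicate 2, DKO replicate 3), so p-values measure only the spread between these samples.

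The groups, the tests, the gene lists and most alternatives were chosen before the data were examined. Cytosines with under 10 reads in any compared library were left out. Levels were computed from summed reads over 500 bp tiles of chromosomes 1 to 19 and X and over promoter windows, each with at least 3 cytosines that met the minimum in every compared library. The gene table (RefSeq, assembly GRCm38.p6, the same assembly as mm10) gives gene starts and ends without strand or transcripts. A promoter window is therefore the gene end with more measured cytosines, from 1 kb outside to 0.5 kb inside the gene. For 57 of 62 genes whose strand was written down from general knowledge (91.9%), the chosen end was the 5′ end, and these genes mostly have CpG islands. Some windows are thus 3′ ends. Their share may be larger among strongly methylated windows, for which it was not checked separately. Windows of neighbouring genes can share cytosines. Exons, introns and UTRs were not assigned. Windows for imprinting control regions were placed at mm10 positions known from the literature, with Mcts2 standing also for H13 and Peg13 for Trappc9.

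DKO and WT lines were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on methylated and unmethylated counts. The model had a term for each library, a group by methylation term and a common dispersion, and two-sided p-values were adjusted by Benjamini-Hochberg. Regions without variation over the lines were not tested, and regions were called at an adjusted p under 0.05. Means of single values over libraries were compared by two-sided exact permutation tests. With 2 against 3 lines there are 10 splits and the smallest p they can give is 0.1, so these tests cannot reach 0.05. The round spermatid library has no replicate, so no p-value was computed for it. A region was called by size where it lay outside the range of all 5 lines and at least 25 percentage points from their mean. The same rule with each single line set against the other 4 gave its background.

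The 9 gene lists hold pluripotency genes, germline genes known to be methylated in somatic cells, spermatid genes, developmental regulators with CpG island promoters, housekeeping genes, feeder fibroblast genes, testis somatic genes, DNA methylation machinery and imprinted genes. The median difference of each list was set against 10000 random lists of its size, matched on the mean level in 10 groups. This percentile describes these libraries and is not a test across replicates. The value of a single housekeeping gene is not reported here.

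Named promoters followed a rule. For DKO against WT, the 10 largest differences per direction were to be named among those called without overlap of the lines, with the unadjusted top 5 per direction as values where fewer were called. This last clause does not say whether the top 5 need an unadjusted p under 0.05. They were first listed without that limit, and the limit was adopted after that list was seen, so both lists are given. For round spermatids the rule took the 12 highest and 12 lowest differences called, passing over clone names, gene models and pseudogenes. It also took up to 4 members per list, every imprinting control region, and the 3 highest and 3 lowest called tiles, with ties broken by position.

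The tests were tried on simulated counts drawn from the levels, depths and spread of the 5 lines, with 200 regions raised in the DKO lines. A raised region kept the relative spread of its level before the rise, so partly methylated regions can vary more than those simulated. Over 28300 tiles, edgeR recovered 0% of tiles raised by 30 percentage points, and over 28302 tiles 29.5% of those raised by 60 points, with 0 false calls in both. Over 9292 promoters it recovered 80.5% of those raised by 30 points with 3 false calls, and over 9249 promoters 90.5% of those raised by 60 points with 18 false calls. limma recovered 44.0% and 63.0% of the tiles, with 27 and 41 false calls. Simulations without any change, 20 for tiles and 20 for promoters, were added after the results were seen. In these edgeR called 0 tiles and 0 to 18 promoters (median 7) and gave 3.21% of tiles and 4.11% of promoters an unadjusted p under 0.05. limma called 4 to 28 tiles (median 16) and 0 to 3 promoters. Simulations with a smaller fixed spread between lines were added after these results were seen. At a spread of 0.01 edgeR recovered 24.0% and 67.5% of the tiles and 18.0% and 33.0% of the promoters. At a spread of 0.001 it recovered 99.5% and 100% of the tiles and 80.0% and 93.5% of the promoters. The rule of size, on 9977 simulated promoters, recovered 100% of 200 raised by 50 points in the round spermatid library and called 29 unchanged ones.

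The alternatives changed the coverage minimum, the number of cytosines, the tile size and the promoter window. They also used limma 3.58.1 on log2(m/(1-m)) with levels m clipped to 0.01 and 0.99, Fisher's exact test on pooled reads, the round spermatid library as an additional group, and a block for lines whose titles share OG3. Other alternatives were other differences for the rule of size, narrower imprinting windows, and each line left out in turn. Other forms of edgeR, a block for lines whose titles share AGH-2, alone and with that for OG3 (which leaves 1 residual degree of freedom among the lines, against 3 in the main model), and imprinting levels over the positions measured in each library were added after the data were seen. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and drawn with matplotlib 3.10.9.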

Results

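RRBS libraries of 2 WT AG-haESC lines, 3 DKO AG-haESC lines and 1 round spermatid sample were compared. Passages were 31 and 18 for WT replicates 1 and 2, and 32, 31 and 29 for DKO replicates 1, 2 and 3. Total read counts over cytosines ranged from 197728785 to 255726544 in the lines and reached 293920118 in the round spermatid library. The median depth of the 233019 cytosines measured in all 6 libraries was between 364 and 503 reads. Levels are percentages of methylated reads, and round spermatid values come from 1 library without replicate. The design implies a comparison of DKO with WT lines and of the lines with round spermatids, which served as the control.

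The elements labelled as deleted were examined first, as a check of the labels. No read fell in the H19 DMR window of any of the 3 DKO lines, which allows up to 0.0149, 0.0146 and 0.0152 RPM (reads scaled to the library total) in DKO replicates 1, 2 and 3. The same window held 22 reads in WT replicate 1, 23 in WT replicate 2 and 347 in round spermatids. In the IG-DMR window, WT replicate 1 had 196 reads at 7 positions, DKO replicate 3 had 62 reads at 2 positions, and WT replicate 2 and DKO replicates 1 and 2 had none. The position of DKO replicate 3 with at least 10 reads, 109525891 on chromosome 12, was the first of the 7 positions of WT replicate 1. A search for runs of at least 3 cytosines with 10 or more reads in both WT lines and none in the DKO lines found 537 runs. None could lie in either window. The H19 DMR window had 1 position with 10 or more reads in each WT line, and the IG-DMR window had no reads in WT replicate 2. The other 9 pairs of lines gave between 540 and 1962 runs of this kind, so the search does not test the deletions, which were not shown at this coverage. The 62 reads of DKO replicate 3, if correctly aligned, go against absence of the whole IG-DMR window from all cells sequenced. That window was placed from the literature, and whether these positions belong to the deleted element was not checked.

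The AG-haESC lines were less methylated than round spermatids, and WT and DKO lines overlapped. Over the cytosines measured in all 6 libraries, the mean level was 8.09% and 4.13% in WT replicates 1 and 2, 5.12%, 7.24% and 5.07% in DKO replicates 1, 2 and 3, and 22.4% in round spermatids. This is 6.11% ± 2.80 (SD, n = 2) in WT and 5.81% ± 1.24 (SD, n = 3) in DKO lines, a difference within the spread of the lines (exact permutation test, two-sided p = 1). Pooled over all cytosines with at least 10 reads, the levels were 6.05% ± 2.87 (SD, n = 2) in WT lines, 6.50% ± 0.860 (SD, n = 3) in DKO lines (p = 1 in the same exact test) and 11.7% in round spermatids (Wilson 95% interval 11.69% to 11.70%). The sign of the difference between DKO and WT thus turned with the cytosines averaged, and the pooled difference was also negative without WT replicate 2 (-1.57 points) or without DKO replicate 2 (-0.0337 points).

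**Figure D1:**
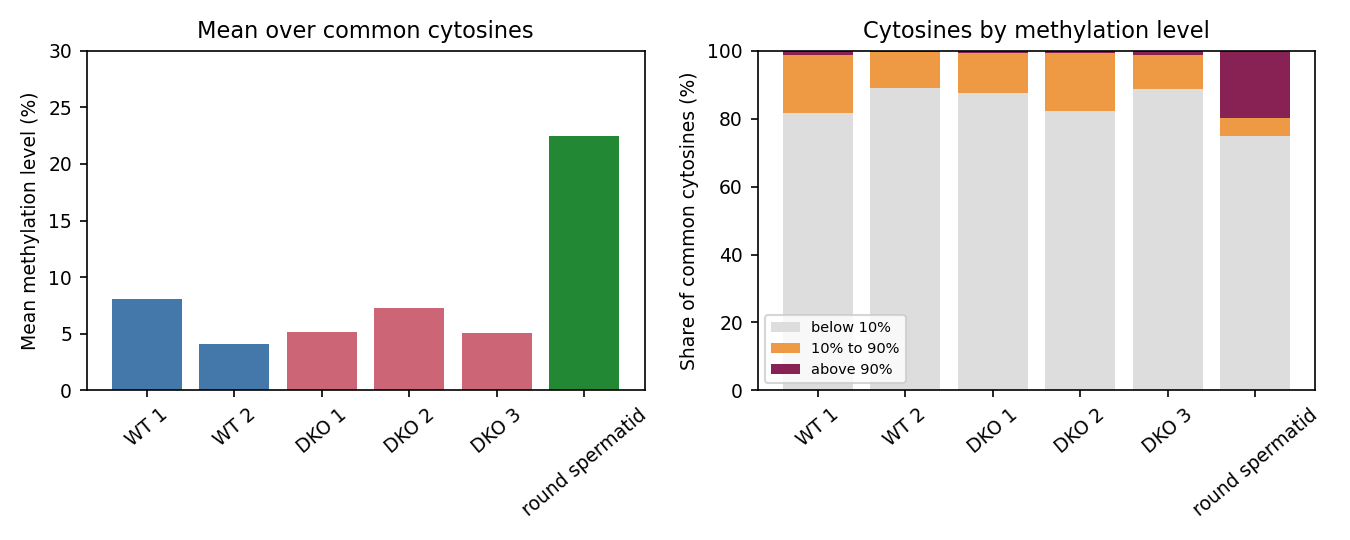
Mean methylation level in percent (left) and share in percent of cytosines in 3 classes of level (right) over the 233019 cytosines measured in all 6 libraries, with 1 bar per library. The 5 lines have means between 4.13% and 8.09% against 22.4% in round spermatids, where 19.7% of these cytosines are above 90%.

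Fully methylated cytosines were common in round spermatids and rare in the lines. In round spermatids 19.7% of the common cytosines were above 90% methylated and 5.42% lay between 10% and 90%. In the lines between 0.457% and 1.37% were above 90% and between 10.1% and 17% lay between 10% and 90%. At the 46001 cytosines above 90% in round spermatids, the mean level was 27.0% and 14.2% in WT replicates 1 and 2, and 17.7%, 24.5% and 17.4% in DKO replicates 1, 2 and 3. At the 174382 cytosines below 10% in round spermatids, the lines had means between 0.982% and 2.15%.

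Gene bodies and sequence outside genes carried most of the methylation in both cell types. Tiles within gene bodies had a mean of 9.48% ± 2.65 (SD, n = 5) in the lines and 38.7% in round spermatids, and tiles outside genes 14.7% ± 3.83 (SD, n = 5) and 47.6%. Tiles at gene ends had 1.10% ± 0.352 (SD, n = 5) and 2.96%. Dense tiles, with at least 10 measured cytosines, were near 0 in both, at 0.456% ± 0.151 (SD, n = 5) and 0.747%.

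Tiles called between round spermatids and the lines were nearly all higher in round spermatids, under a rule that left less room for lower calls. A lower call needed a mean of at least 25% in the lines, whose mean over all tiles was 6.49%. Of 27005 tiles, 6748 (25%) were higher and 118 (0.437%) lower by the rule of size. The higher tiles had a median level of 99.6% in round spermatids and a median of 17.1% for the mean of the lines. Of 5455 tiles at 80% or more in round spermatids, 2974 had a mean below 20% over the lines, 1073 were below 20% in every line and 8 were at 50% or more in every line. None (0) of the tiles was below 10% in round spermatids and at 50% or more in all 5 lines. A single line set against the other 4 gave between 198 and 1319 higher and between 116 and 611 lower tiles. The number lower in round spermatids lay within that range, and was 187 without WT replicate 2. The number higher lay above it.

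Of the called tiles, 3 that stood at 100% in round spermatids and 0% in all 5 lines lay within Jmjd1c (chromosome 10, 67103501 to 67104000), Nuak1 (chromosome 10, 84388501 to 84389000) and Triobp (chromosome 15, 78977001 to 78977500). Jmjd1c encodes a histone demethylase family protein, Nuak1 a kinase and Triobp an actin-binding protein. The tiles held 4, 3 and 3 measured cytosines, with at least 356, 72 and 36 reads in every library. The lowest tile was at 0.244% in round spermatids and 64.7% ± 27.2 (SD, n = 5) in the lines, on chromosome 6 from 147127001 to 147127500, 14223 bp from Klhl42. The next were at 0.229% against 62.4% ± 18 (SD, n = 5) on chromosome 3 (59431001 to 59431500, 86563 bp from Igsf10) and at 1.57% against 56.2% ± 19.4 (SD, n = 5) within Sdccag8 on chromosome 1 (176899501 to 176900000).

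Of 9977 promoter windows, 326 were higher and 7 lower in round spermatids under the same rule. Single lines gave 10 to 94 higher and 2 to 27 lower windows. Only 95 of the 9977 windows had a mean in the lines high enough for a lower call. The numbers higher and lower in round spermatids therefore cannot be set against each other. The widest gap was at Bnip1, a SNARE protein gene on chromosome 17, whose window from 26792022 to 26793521 was at 100% in round spermatids and 1.67% ± 3.73 (SD, n = 5) in the lines, from 3 cytosines and at least 84 reads. Eef2kmt, which encodes a methyltransferase of elongation factor 2, was at 99.9% against 2.83% ± 4.51 (SD, n = 5). Syna, which encodes the placental fusion protein syncytin A, was at 100% against 3.50% ± 3.75 (SD, n = 5). Klrb1f, a gene of the killer cell lectin-like receptor family, was at 95.5% against 0.417% ± 0.852 (SD, n = 5). Irf7, a transcription factor of the interferon response, was at 99.9% against 5.24% ± 4.87 (SD, n = 5), and Tlr12, a toll-like receptor gene, at 100% against 5.81% ± 5.36 (SD, n = 5).

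The other named windows were also near full methylation in round spermatids. Tmem52 was at 99.9% against 4.02% ± 2.76 (SD, n = 5) in the lines and Tmem121 at 99.9% against 4.32% ± 9.36 (SD, n = 5). Elane, which encodes neutrophil elastase, was at 100% against 5.07% ± 11.3 (SD, n = 5), where WT replicate 1 was at 25.2%. Nfam1, which encodes an immune receptor, lay 94.8 percentage points above a mean of 5.14% ± 7.05 (SD, n = 5). Zswim1 and Spata25 share their measured cytosines, at 100% against 6.35% ± 9.96 (SD, n = 5). These windows held 3 to 5 cytosines, and that of Klrb1f 7. The gene table gives no strand, so any of them can lie at the 3′ end of its gene.

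Of the 7 promoter windows lower in round spermatids, 3 had names that the rule allows. Taar4, a trace amine receptor gene, was at 2.33% in round spermatids and 48.9% ± 11.4 (SD, n = 5) in the lines. Ppp1r14bl was at 0.0460% against 39.2% ± 19.9 (SD, n = 5), and Wfdc15a at 5.06% against 42.6% ± 21.3 (SD, n = 5). The number lower lay within the range of single lines and was 15 without WT replicate 2, 11 without DKO replicate 1 and 12 without DKO replicate 3.

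**Figure D2:**
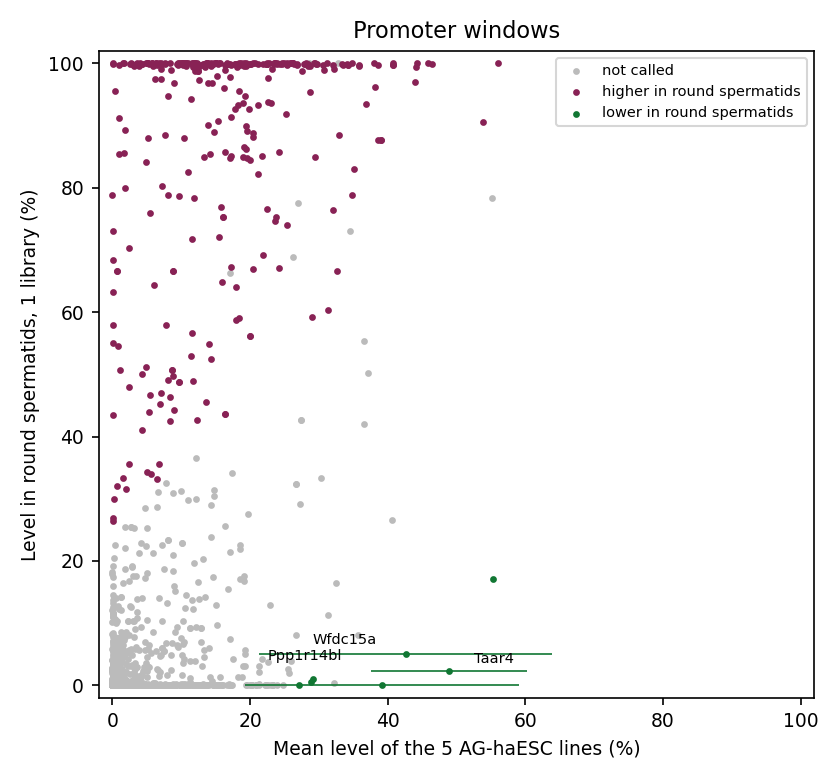
Methylation level in percent of 9977 promoter windows in round spermatids (vertical axis, 1 library) against the mean of the 5 AG-haESC lines (horizontal axis), with horizontal bars of 1 SD over the lines for the 3 named lower windows. The 326 higher windows lie towards the top left and the 7 lower ones along the bottom.

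Germline genes had a lower mean level in the round spermatid library than in the lines, which no test supports. The rule of size could not call any of them lower, since none had a mean of 25% or more in the lines, nor any member of the other lists apart from 1 spermatid gene. The 10 measured genes had a mean of 0.267% in round spermatids and 6.42% ± 2.40 (SD, n = 5) in the lines, and their median difference of -2.50 percentage points lay at percentile 5.12 of random lists. Taf7l, which encodes a germ cell subunit of a transcription factor on the X chromosome, was at 0% against 23.3% ± 10.6 (SD, n = 5). Dazl, an RNA-binding protein gene of germ cells, was at 0.0265% against 12.9% ± 8.75 (SD, n = 5), Asz1 at 0.0219% against 13.2% ± 7.91 (SD, n = 5) and Mael at 0.652% against 3.92% ± 3.95 (SD, n = 5). The 23 developmental regulators had a mean of 0.0242% against 1.45% ± 0.975 (SD, n = 5) and a median difference of -0.371 points, at percentile 0.5. Among them Tbx5, a heart and limb factor, was at 0% against 15.3% ± 24.5 (SD, n = 5), where DKO replicate 3 alone was at 58.2%. Sox17, an endoderm factor, was at 0% against 3.30% ± 3.10 (SD, n = 5).

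Of 9 measured spermatid genes, 2 were higher in round spermatids, with a median at percentile 77.8. They were the neighbouring kinase genes Tssk1, at 99.9% against 22.4% ± 18 (SD, n = 5), and Tssk2, at 100% against 29.3% ± 21.1 (SD, n = 5). Tnp1, which encodes a transition protein that replaces histones in spermatids, was at 0% against 12.1% ± 10.1 (SD, n = 5), and Spata3 at 0.0787% against 2.32% ± 3.16 (SD, n = 5). Of 4 measured testis somatic genes 1 was higher, with a median at percentile 78.5. It was Clu, which encodes clusterin, at 100% against 15.6% ± 5.72 (SD, n = 5), while Amh, a Sertoli cell hormone gene, was at 0.00947% against 0.680% ± 0.456 (SD, n = 5). By coordinate, the window of Tssk1 lies at the start of the gene and those of Tssk2 and Clu at the end. Without strand, any of these windows can be a 3′ end, so methylation of the promoters themselves was not shown.

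No promoter of the remaining lists (0) was called higher in round spermatids. The 9 measured pluripotency genes had means of 0.903% in round spermatids and 0.0454% in the lines, at percentile 97.6, where Utf1, a pluripotency factor, was at 7.13% against 0.0375% ± 0.0426 (SD, n = 5). The 14 housekeeping genes had means of 0.235% and 0.0349%, at percentile 99.0. The 8 feeder fibroblast genes had means of 0.0387% and 3.52%, at percentile 23.2, where Pdgfrb, a growth factor receptor gene, was at 0% against 15.2% ± 22.3 (SD, n = 5). The 6 genes of the DNA methylation machinery had means of 0.0434% and 0.0515%, at percentile 88.1, and the 21 imprinted genes 0.123% and 0.179%, at percentile 56.6. Percentiles refer to the median difference, which differed in sign from the difference of the means for spermatid genes, testis somatic genes and the methylation machinery.

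Between DKO and WT lines no promoter passed the main test, and the widest separations among those with an unadjusted p under 0.05 are given as values. The gene table gives no strand, so any window named for this comparison can lie at the 3′ end of its gene. Arrdc5, an arrestin domain gene on chromosome 17 (window 56293111 to 56294610, 8 cytosines), was at 0.756% and 3.30% in the WT lines and at 54.6%, 30.3% and 20.1% in the DKO lines. Ccdc185 had means of 2.60% in WT and 32.1% in DKO lines, Zfp628, a zinc finger gene, 0.182% and 23.8%, Lrfn3 1.35% and 17.8%, and Gria1, which encodes a glutamate receptor subunit, 0.836% and 15.1%. Foxi3, a forkhead factor, was at 8.51% and 39.6% in the WT lines and at 0.148%, 0.347% and 0.209% in the DKO lines. Syne4 and Alkbh6 share a window at 44.4% and 3.94% in the WT lines and a mean of 0.0326% in DKO lines. Rusc2 and Fam166b have overlapping windows, with means of 24.1% and 21.4% in WT lines, WT replicate 1 being at 39.7% and 38.8%, and 0% in DKO lines.

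The adjusted p of edgeR was 0.983 for Arrdc5 and 0.278 at the lowest over all promoters. Without a limit on the unadjusted p, the largest differences without overlap were higher in DKO lines at Cit, Arrdc5, Ccdc185, Mrps15 and Oscp1. They were lower at Lcat, Cort, Fam243, Tomm40l and Krt73. Cit, which encodes citron kinase, had means of 5.80% in WT and 39.9% in DKO lines, where DKO replicate 2 was at 79.7%. Lcat, which encodes an enzyme of cholesterol esterification, had 55.4% and 11.4%, and Cort, which encodes cortistatin, 39.7% and 1.25%, where WT replicate 1 was at 86.7% and 75.8%.

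**Figure D3:**
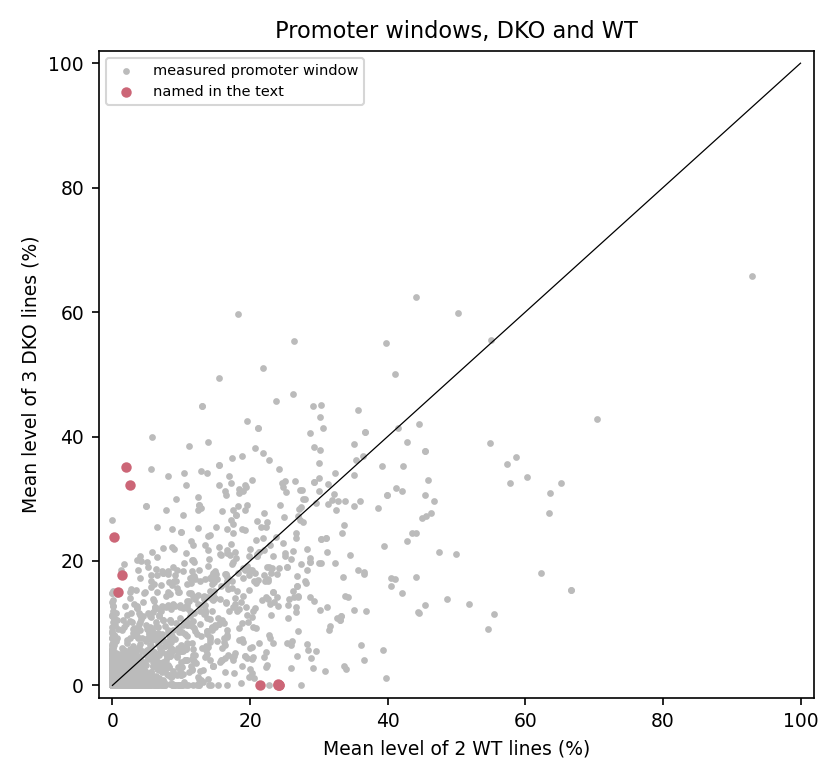
Mean methylation level in percent of promoter windows in the 3 DKO lines (vertical axis) against the 2 WT lines (horizontal axis), with the line of equality and the 10 windows named among those with an unadjusted p under 0.05 in red. Most windows lie near 0 in both, and the named ones, such as Arrdc5 at 2.03% in WT and 35.0% in DKO lines, lie at the edges of the cloud.

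Of 9794 tested promoters, edgeR called 0 and gave 256 an unadjusted p under 0.05, against 321 to 422 in 20 simulations without any change. limma called 0 with 77 unadjusted. Of 29763 tested tiles, edgeR called 0 and gave 662 an unadjusted p under 0.05, against 863 to 967 in such simulations, while limma called 5 higher and 22 lower in DKO lines with 729 unadjusted. Other forms of edgeR called up to 149 tiles and 41 promoters (the likelihood ratio test), and Fisher's exact test on pooled reads, which ignores the spread between lines, called 15887 and 3019. With blocks for both line names that titles of WT and DKO lines share, OG3 and AGH-2, edgeR called 1 tile higher and 1 lower and 8 promoters higher and 5 lower in DKO lines, a model added after the results were seen that leaves 1 residual degree of freedom. In 20 simulations without any change it called 0 tiles and 0 to 10 promoters. The DKO and WT values did not overlap at 14.9% of tiles (2792 higher and 1870 lower in DKO lines) and 16.9% of promoters (1314 higher and 429 lower). Chance would give 20% if no values were tied. Tied regions, among them 1470 tiles and 522 promoters without variation, were counted as overlapping. The share by chance is thus below 20%, and these shares cannot be set against it. Over all regions the median absolute difference between DKO and WT was 0.512 points for tiles and 0.0271 points for promoters. The direction of the regions without overlap was not tested. Differences of at least 25 percentage points were found at 877 tiles (369 higher and 508 lower in DKO lines) and 45 promoters (14 and 31), against 788 to 1585 tiles and 36 to 80 promoters in the other 9 splits of the lines, and their direction was not tested. In simulations with the spread of these lines edgeR recovered 0% of tiles and 80.5% of promoters raised by 30 percentage points. Without any change edgeR called 0 tiles and 0 to 18 promoters, and limma 4 to 28 tiles, a range that includes the 27 it called here. In these simulations limma gave 900 to 1000 tiles an unadjusted p under 0.05, against 729 here. The simulations thus differ from the data, and they cannot show that the 27 arise without any change.

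The 5 tiles that limma called higher, named after their values were seen, lay within Xpnpep1, Igf2bp1 and Trim11 and nearest to Nt5c1b and Fbxo31. Another tile within Xpnpep1 was called lower, at 5.72% and 5.02% in the WT lines and 0%, 0.0864% and 0% in the DKO lines. Igf2bp1 encodes an RNA-binding protein, and its tile (chromosome 11, 95957001 to 95957500) was at 0% in both WT lines and at 26.8%, 32.2% and 29.7% in the DKO lines. The tile in Trim11 was at 0% in both WT lines and at 33.6%, 37.1% and 33.3% in the DKO lines. The 22 tiles called lower differed by between -43.9 and -1.91 percentage points. The widest lay within Slc7a10, at 42.6% and 45.3% in the WT lines and 0% in the DKO lines, and within Hr, at 33.3% and 31% against 0%, also named after their values were seen. The adjusted p of edgeR was 1 for each of the 27.

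Every gene list had 0 promoters called between DKO and WT, over all promoters and adjusted over the list alone. Spermatid genes stood farthest from random lists. Their 10 measured promoters had means of 18.3% and 4.25% in the WT lines and 5.18%, 8.13% and 5.26% in the DKO lines, and a median difference of -3.34 percentage points, at percentile 0.06. Without WT replicate 1 the median difference was 0.249 points, so its sign rested on that line. The 11 germline genes had means of 6.85% in WT and 5.69% in DKO lines and a median difference of -2.01 points at percentile 6.99, which became 0.158 without WT replicate 1 and 0 without WT replicate 2.

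Pluripotency promoters were near 0, with means of 0.0125% in WT and 0.0598% in DKO lines over 10 genes (percentile 80.9). At Tet1, which encodes an enzyme that oxidises methylcytosine, the means were 0% and 0.0757%. The DNA methylation machinery, 7 genes, had means of 0.0607% and 0.0420% (percentile 64.9), and 14 housekeeping promoters 0.0343% and 0.0382% (percentile 87.0). The 22 imprinted genes had means of 1.36% and 0.0693% (percentile 15.3), where WT replicate 1 was at 2.48% and WT replicate 2 at 0.242%. Among them Ascl2, a placental transcription factor gene, had 2.12% and 0.0271%, and Nnat 1.49% and 0.192%. Over the 21 imprinted genes also measured in round spermatids, the mean of the lines was 0.179% and the highest gene mean 0.925%. The gap between the means of the imprinted genes thus rested mostly on sequence not measured in round spermatids, not on the list as a whole. The gene or genes behind it were not identified. The 23 developmental regulators had 1.42% and 2.24% (percentile 17.3), the 8 feeder fibroblast genes 3.09% and 3.82% (percentile 21.0), and the 4 testis somatic genes 3.97% and 4.29% (percentile 52.8). Median and mean differences had opposite signs for feeder fibroblast genes (-0.000575 and 0.732 points), the methylation machinery (0.0227 and -0.0187 points) and imprinted genes (0.00257 and -1.29 points).

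Maternally methylated imprinting control regions were low in all 6 libraries at the cytosines common to them. Of 19 such regions 16 had at least 3 cytosines measured in every library, with 203 cytosines in all. Their mean level was 0.650% and 0.364% in WT replicates 1 and 2, 0.0406%, 0.348% and 0.324% in DKO replicates 1, 2 and 3, and 0.111% in round spermatids. The difference of -0.270 percentage points between DKO and WT had a two-sided exact permutation p = 0.2. The highest value was 5.83%, at Gnas XL (chromosome 2, 174298129 to 174300328, 18 cytosines) in WT replicate 1. With narrower windows about the same centres, 14 regions were measured, the highest value was 15% and the difference -0.508 points (exact permutation p = 0.3). Grb10 reached 2.71% in WT replicate 2 and 2.58% in DKO replicate 2, Impact 2.73% in DKO replicate 3, Gnas 1A 2.29% and Nnat 1.42% in WT replicate 1, and Zrsr1 0.928% in WT replicate 2. Airn, Kcnq1ot1, Peg10, Snrpn, Mcts2, Nap1l5, Inpp5f, Cdh15, Plagl1 and Slc38a4 were at or below 0.564% in every library at the common cytosines. Mest, Peg3 and Peg13 had too few common cytosines.

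Over all positions with at least 10 reads in a library, which differ between libraries, some regions were higher. Mest was at 45.6% over 7 positions in DKO replicate 1 (140 of 410 reads methylated in the window) and at 16.7% over 6 positions in WT replicate 1 (29 of 1397 reads). Cdh15 was at 11% over 16 positions in DKO replicate 1 (197 of 861 reads), Gnas XL at 7.64% over 54 positions in WT replicate 1, and Grb10 at 12.5% over 27 positions in round spermatids (66 of 20066 reads). All other values of maternally methylated regions were at or below 3.23%. The mean over 18 regions was then 1.63% and 0.355% in the WT lines, 3.21%, 0.259% and 0.375% in the DKO lines and 0.841% in round spermatids, so the difference between DKO and WT turned to 0.290 points (exact permutation p = 0.9).

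**Figure D4:**
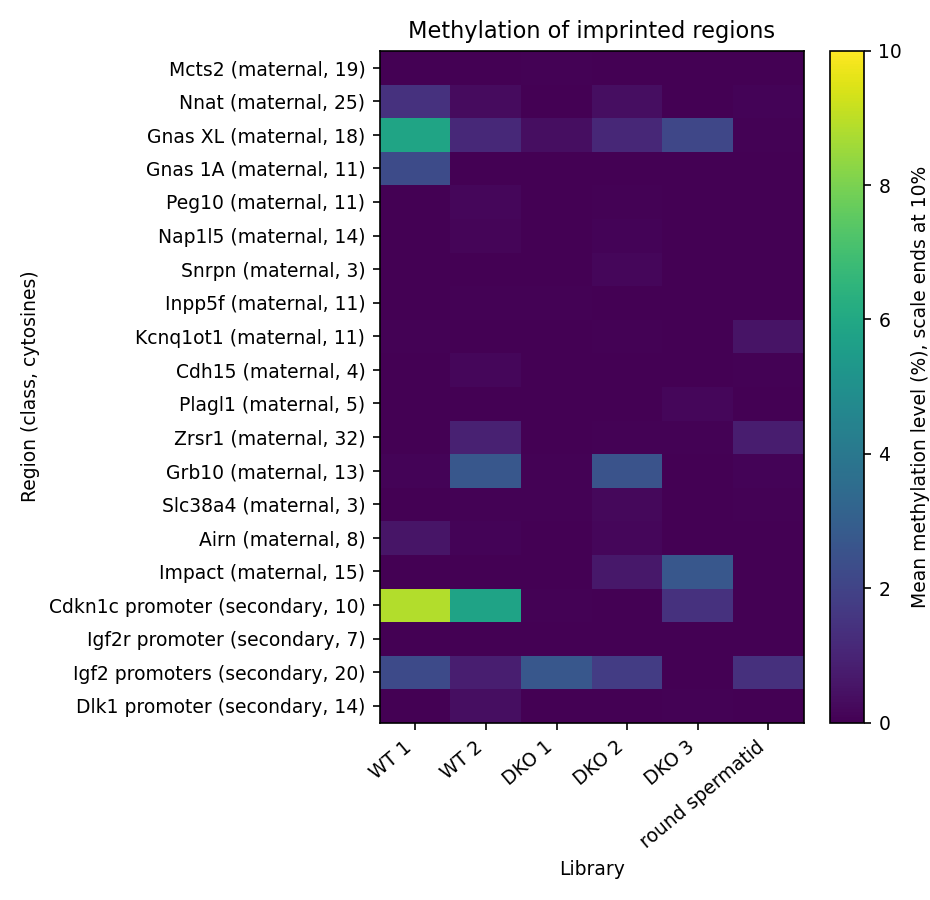
Mean methylation level in percent (colour, scale from 0 to 10) of 16 maternally methylated control regions and 4 secondary imprinted promoter regions, named with their number of common cytosines, in the 6 libraries. The highest value is 8.85%, at the Cdkn1c promoter in WT replicate 1.

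Secondary imprinted promoters were low as well at the common cytosines. The promoter of Cdkn1c, a cell cycle inhibitor gene expressed from the maternal allele (chromosome 7, 143458936 to 143459376, 10 cytosines), was at 8.85% and 5.81% in the WT lines. It was at 0.0730%, 0.0127% and 1.42% in the DKO lines and at 0.0248% in round spermatids, and no test was made of this region alone. The Igf2 promoters were at 2.24% and 0.821% in the WT lines, 2.70%, 1.76% and 0.0238% in the DKO lines and 1.37% in round spermatids. Over all positions of each library with at least 10 reads, the Igf2 promoters were at 11% in round spermatids (33 positions, 484 of 31644 reads methylated in the window), and the Cdkn1c promoter was at 3.28% and 8.32% in the WT lines. The Igf2r and Dlk1 promoters were at or below 0.389% in every library, and the Meg3 and H19 promoters had no common cytosine.

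Paternally methylated control regions were hardly covered, and 0 of the 4 had 3 common cytosines. At the H19 DMR all 347 reads of round spermatids, at position 142582678 of chromosome 7, were methylated. None of the 22 and 23 reads of WT replicates 1 and 2 was methylated, which allows up to 13.6% and 13%, and these lay mostly at 142581387, so no position was compared between the cell types. At the IG-DMR none of the 196 reads of WT replicate 1, counted over 7 positions, was methylated, which allows up to 1.53% if all counts are independent. At Rasgrf1 between 0 and 318 reads fell in the window per library. At Zdbf2 311 of 576 reads were methylated in WT replicate 1 and 1 of 332 in WT replicate 2. In DKO replicates 1, 2 and 3 these were 208 of 964, 246 of 323 and 2 of 178, and in round spermatids 227 of 479, at differing positions.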

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

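The tests of explanations in this part were chosen only after the results were seen, although the use of maternal imprinting regions to limit a share of other cells had been planned. They concern reads outside the main comparisons, namely those on the mitochondrial genome and on chromosome Y.

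In DKO replicate 1, 1.99% of mitochondrial reads were methylated (1609 of 81030, Wilson 95% interval 1.89% to 2.08%), above 0.0182% and 0.00759% in the WT lines. Incomplete bisulfite conversion would raise unmethylated regions elsewhere, yet the maternal imprinting control regions of this library had a mean of 0.0406% over common cytosines, the lowest of the 5 lines. Over all its positions Cdh15 and Mest were higher in this library, at 11% and 45.6%, while none of 7599 reads at Kcnq1ot1 was methylated, so a raised level throughout was not seen. A few amplified fragments may be the source, since 98.5% of the methylated reads lay in 4 of the 16 clusters of positions that held any. The 4 clusters were picked after looking at the counts, and no biological explanation was tested.

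Reads in the first 2 Mb of chromosome Y were above both WT lines (0.114 and 0.149 RPM) in DKO replicates 1, 2 and 3 at 0.223, 0.350 and 0.754 RPM and in round spermatids at 47.3 RPM. Wilson 95% intervals were 0.167 to 0.298, 0.278 to 0.441, 0.642 to 0.885 and 46.5 to 48.1 RPM, against upper bounds of 0.168 and 0.204 in the WT lines, so that of DKO replicate 1 overlapped the WT intervals.

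The higher methylation of the round spermatid library was weighed as a pattern of the main comparison. Incomplete conversion would leave mitochondrial reads methylated, and 0.0280% of them were in this library. Somatic testis cells, which carry maternal chromosomes, would raise the maternal imprinting regions, and their mean level over common cytosines allows a share of 0.222% of cells with both parental sets. Grb10 was at 12.5% over all its positions, from 66 of 20066 reads, yet such cells would raise the other regions alike, and at Mcts2 5 of 52487 reads were methylated. A single deviating library stays open, as single lines gave up to 1319 higher tiles and no replicate of round spermatids was analysed. The cell type itself remains among the open explanations, and so does the culture of the lines. Per the labels, every line grew on feeder cells in ES medium with kinase inhibitors, while the round spermatids came from testis. Culture and cell type therefore cannot be told apart with these samples.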

How the results depend on the processing

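The other forms of edgeR, the blocks with AGH-2 and the imprinting levels over the positions of each library were chosen after seeing the data, and the remaining alternatives before. Calls between DKO and WT stayed at 0 under other coverage minimums, numbers of cytosines, tile sizes and windows, with the round spermatid library added, with the replicate block of OG3 lines, with a block of AGH-2 lines, and with each line left out (0 to 0 tiles and 0 to 0 promoters). With blocks for both line names, which leave 1 residual degree of freedom, 2 tiles and 13 promoters were called. With a lone WT line, that line is assumed to vary like the DKO lines. The test mattered: limma called 27 tiles, the newer quasi-likelihood test of edgeR 1 tile and 2 promoters, its likelihood ratio test 149 and 41, and Fisher's exact test on pooled reads 15887 and 3019. Fisher's test counts reads, not lines, and the cause of the other differences was not tested. Robust shrinkage, a trended dispersion and a dispersion fixed at 0.05 called 0.

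Counts and shares for round spermatids moved with the number of cytosines required. With at least 1 cytosine 25663 tiles (44.5%) were higher and 322 lower, and 949 promoters (7.95%) higher and 25 lower. With at least 5 these were 1462 (9.56%), 29, 83 (1.01%) and 3, against 25% of tiles and 3.27% of promoters higher in the main setting, so the number of regions does not account for the move. A difference of 20 points gave 195 lower tiles and 16 lower promoters, and one of 40 points 19 and 1. Leaving out each line gave 7042 to 7577 higher and 116 to 187 lower tiles, and 342 to 368 higher and 8 to 15 lower promoters. The differences of the 15 named genes moved by less than the spread of the lines in all 132 values computed, which is a weak check. On the same cytosines, leaving out 1 of 5 lines can shift their mean by only part of that spread. Another number of cytosines only drops or adds windows and repeats the values of the others. With at least 5 cytosines, only Klrb1f, Nfam1, Taar4 and Ppp1r14bl of these genes were still measured.

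The global difference between DKO and WT reversed from 0.453 to -0.298 points over common cytosines and ranged from -1.57 to 2.48 with lines left out, being -1.57 without WT replicate 2 and -0.0337 without DKO replicate 2. The cause was not tested. Round spermatids minus lines moved from 5.38 to 16.5 points over common cytosines and ranged from 4.80 to 5.82. The imprinting difference of -0.270 points was -0.508 in narrower windows, ranged from -0.413 to -0.165 with lines left out and reversed to 0.290 over the positions of each library. The search for lost runs gave 194 with at least 5 cytosines of 5 reads. With the other window no list had a promoter called either, and medians moved by less than the spread of the lines. The median of feeder fibroblast genes nevertheless changed sign (to 0.000137). The percentile of testis somatic genes moved from 52.8 to 77.6 and that of pluripotency genes from 80.9 to 66.7. That of developmental regulators moved from 17.3 to 31.9 and that of germline genes from 6.99 to 13.4.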

Other observations

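The tests in this part, other than the block for OG3 lines, were chosen only after the results were seen.

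Over common cytosines, chromosome X was less methylated than the autosomes in round spermatids and more methylated in each of the 5 lines. Over 4848 common cytosines of chromosome X, the mean level was 18% in round spermatids against 22.5% on the autosomes. In the lines the values ranged from 4.65% against 4.11% in WT replicate 2 to 8.93% against 8.06% in WT replicate 1. With reads pooled over all cytosines with at least 10 reads, the direction in round spermatids reversed, at 12.3% on chromosome X against 11.7% on the autosomes, while each line stayed higher on chromosome X. The share of reads on chromosome X in round spermatids was 0.549 of the mean share of the lines. Near the targeted IG-DMR, the Meg3 promoter had no reads in either WT line and 149, 516 and 82 reads in DKO replicates 1, 2 and 3, of which 0, 14 and 0 were methylated. Uneven coverage was common, as 857968 positions reached 10 reads in exactly 1 library. Whether this coverage relates to the deletion was not tested.

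Reads were missing over 8 long stretches in single lines, each of at least 6 clusters of cytosines that the other 4 lines all covered. In DKO replicate 3 they lay on chromosome 2 from 178023527 to 178678225 (Phactr3, Sycp2, Cdh26 and 4 other protein-coding genes, 2 reads against at least 42212 in any other line), from 178728645 to 179179296 and from 179798245 to 180025975 (Cdh4, Taf4, Lsm14b), and on chromosome 14 from 17534204 to 17792553 (Thrb). In WT replicate 2 they lay on chromosome 1 from 77258878 to 78149797 (Epha4 and part of Pax3, 7 reads against at least 16148) and on chromosome 13 from 65867220 to 66027589. In DKO replicate 2 a stretch on chromosome 5 from 115095085 to 115175504 (Sppl3, Acads, Unc119b, Mlec, Cabp1) held 1155 reads against at least 35804. In DKO replicate 1 a stretch on chromosome Y from 90741268 to 90803199 held 0 reads against at least 66350. The first 2 Mb of chromosome Y held only 26 to 149 reads in the lines. Reads aligned to the stretch therefore do not show that the lines carry this chromosome, and their origin was not tested. The minimum of 6 clusters followed a look with 4, which gave 17 stretches.

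Scattered loss of fragments would give 0.00243 such stretches in the 5 lines together, if neighbouring clusters were lost independently, which was assumed and not tested. At the 5 stretches with no other lost stretch of the same line within 300 kb and with covered flanks, flanks of 300 kb held between 61.4% and 160% of the reads of the other lines, from 7 cytosines at the fewest. This speaks against low coverage of the whole neighbourhood there. Inside these stretches, positions not used to find them held between 0.0197% and 9.82%, which a deletion in most cells of the line would give, although the same data suggested it and no independent measurement was made. At the other 3 the explanation stays open: the neighbouring pair on chromosome 2 had 21.7% and 73.6% in the flanks and up to 9.40% inside, and the stretch on chromosome Y had no flank to compare. This division followed 3 earlier forms of the test that disagreed. Joining neighbours within 1 Mb gave 74.9% in the flanks and 27.0% inside, where covered sequence between the stretches was counted, the stretch with most clusters gave 21.7% and 0.0181%, and medians gave 77.9% and 0.208%. No biological explanation by group was tested.

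For DKO against WT, 2 against 3 lines make 10 splits, too few for a share under 0.05. Of these splits, 7 gave as many tiles with an unadjusted p under 0.05 (662 in the real split, 1260 at the highest of the others) and 8 gave as many promoters (256 in the real split, 495 at the highest of the others). The split that sets the lines whose titles share OG3, WT replicate 1 and DKO replicate 2, against the rest gave these 495 promoters, called 21 of them and gave 1232 tiles. This may point to a structure of the samples, but it was read from the highest of the splits. In 20 simulations without any change between 0 and 18 promoters were called. Those simulations gave 321 to 422 promoters an unadjusted p under 0.05 against 256 in the real split. They thus differ from the data and cannot gauge the 21. The OG3 lines share a name and also had the highest pooled levels of the 5, 8.07% and 7.47%. The split of WT replicate 2 and DKO replicate 3, whose titles share AGH-2, gave the 1260 tiles and called 0 promoters, and that of WT replicate 2 and DKO replicate 1 called 4 promoters. Every remaining split called 0 promoters. Pearson's r of the levels was the highest of all pairs of lines for the OG3 pair, at 0.426, and the lowest for the AGH-2 pair, at 0.280, but both OG3 lines reached higher values with the round spermatid library, 0.490 and 0.488, so a high r is not specific to the shared name. With a block for OG3 lines edgeR called 0 tiles and 0 promoters between DKO and WT (884 and 441 with an unadjusted p under 0.05), and with blocks for both names 2 tiles and 13 promoters (1147 and 384), where 20 simulations without any change called 0 tiles and 0 to 10 promoters. That model has 1 residual degree of freedom, and the simulated lines had no structure by name, so whether the 13 differ between DKO and WT stays open.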
